A study of Homo sapiens with 10 samples.

How the data were processed

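Gene expression was measured on Illumina BeadChip arrays in OCI-LY10, a human cell line of the activated B-cell subtype of diffuse large B-cell lymphoma. Per the labels' protocols, cells received 1 micromolar CC-122 or its solvent DMSO for 18 hours, RNA was extracted with a Qiagen miRNeasy kit, and biotin-labelled RNA was made with an Illumina TotalPrep kit. Each group held 5 arrays, numbered 1 to 5 in the labels. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

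The authors deposited a probe intensity for each of 48107 probes on each of the 10 arrays, with no normalization per the file name, on a linear scale. The deposited table also gives a detection p-value per probe and array. The scanner software and its version are not given in the sources used here. Normalized values that the authors deposited separately, on a log2 scale judging by their range, cover 34468 probes, and the rule that chose those probes is not given in the sources used here. Set against the values computed here, the 10 columns each matched their own array best, with a correlation across probes of at least 0.99993 and a median difference of 0.044 log2 units. Each of the 10 columns had a median of 4.54. The match settles the log2 scale and the direction and shows no centring of genes, while the normalization method stays unknown, and these values were used only as an alternative. 1 probe lacked a value on an array and was left out.

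Intensities were normalized with neqc of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values, adds an offset of 16 and applies quantile normalization. Probes were named through the platform's gene table, with symbols updated through gene identifiers to those of the GRCh38.p14 annotation. That table held 26362 probes, of which 26359 had 1 gene and 3 had several, and 21745 deposited probes were not listed there and stayed unnamed. Identifiers of 26326 probes matched the annotation and 36 did not. A probe was kept if its detection p-value was below 0.05 on at least 5 arrays, which left 17125 probes. The probe with the highest mean over the arrays stood for its gene, which gave 9041 genes. Of these, 2221 had several kept probes.

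CC-122 was compared with DMSO by limma (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all genes tested, and a gene was called when its adjusted p was below 0.05. Errors of log2 fold changes are standard errors from this fit, and group means are given with their SD. Where a probe was not detected on any array of a group, the fold is a lower bound: the bright group's mean was set against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal, with the adjusted p from the fit. Where some arrays of a group detected the probe, their number is given.

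The analysis plan was fixed before the data were examined: the test, the alternatives, 24 gene lists written from textbook knowledge, and the rule for named genes. That rule took the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap, up to 4 called members of each list with the largest change, and CRBN, IKZF1, IKZF3, IRF4, IRF7, MYC and TNFSF10 whatever their values, with 1 further gene that is not reported here. It gave 81 genes. For 20 of these several probes were kept, and none had probes of opposite direction. Other genes named in the text were chosen after their values were seen, apart from counts by list. IKZF1 had no probe named here and was not analysed here.

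Each list was compared with all other genes tested by camera of limma with a preset inter-gene correlation of 0.01, adjusted over the 24 lists. Camera with an estimated correlation and fry were alternatives. The lists covered interferon-stimulated genes, interferon signalling, MHC class I and class II presentation, the cereblon pathway and its substrates, NF-kB targets, B-cell receptor signalling, B-cell identity, plasma cell differentiation, G2/M and mitosis, DNA replication, cell cycle inhibitors, apoptosis, p53 targets, MYC and ribosome biogenesis, the unfolded protein and integrated stress response, cholesterol biosynthesis, glycolysis and hypoxia, immediate early and heat shock genes, and cytoskeleton, adhesion and costimulation. A further 4 held markers of T and NK cells, monocytes and macrophages, erythroid cells and platelets, and fibroblasts and epithelia, which the culture should not hold.

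The calculation was tested on simulated data made from these arrays, in which 11240 genes passed the filter. It recovered 77 of 95 genes changed about 1.5-fold (81.1%) and 89 of 92 changed by 1 log2 unit (96.7%), with 3.49% false calls. The simulated noise was independent between genes, and more genes passed than the 9041 of the real arrays. The share of false calls need not hold for the real data. The alternatives were other background corrections, median scaling, the authors' normalized values, other filters and probe rules, array weights, an intensity trend, the replicate number as a block, and each array left out in turn. In 1 of them the background was estimated without the detection p-values and the offset was 50 in place of 16. It is called the fixed offset or fixed background offset below. An array left out was left out of the fit alone, so normalization, filter and choice of probe still used all 10 arrays. A slide block was not run because the files give no slide positions. Scan dates were not analysed here. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.09.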

Results

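The data were 10 arrays of OCI-LY10 cells, 5 after 18 hours with 1 micromolar CC-122 and 5 after DMSO. CC-122 (avadomide) is a drug that binds cereblon, the substrate receptor of a ubiquitin ligase, and leads to loss of the lymphoid transcription factors Ikaros (IKZF1) and Aiolos (IKZF3) as proteins. The series title sets the compound beside the interferon response, and the comparison asks which transcripts differ between treated and vehicle cells. Between 18043 and 18844 probes were detected per array. Median raw intensities lay between 74.0 and 81.6 except on CC-122 replicate 3, where the median was 108.9. No pair of arrays held identical raw intensities. After normalization, arrays of the same group correlated at 0.989 to 0.993 across the genes tested, and the first principal component, with 40.7% of the variance, separated the groups.

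Interferon-stimulated genes rose after CC-122, and MX1, CXCL10 and ISG15 were among the 4 largest rises of all genes tested. MX1, an antiviral GTPase, was not detected on any DMSO array and was at least 15.9-fold higher after CC-122 (adjusted p = 6.39e-11). CXCL10, a chemokine that attracts T cells, rose 7.36-fold from 5.00 ± 0.13 to 7.88 ± 0.07 on the log2 scale (SD, n = 5 in each group), and ISG15, a ubiquitin-like modifier, rose 5.72-fold. These sizes, and the bound of MX1, depend on the background correction. With the alternative correction and its offset of 50 (the fixed offset), the log2 changes were 2.77 (MX1), 1.86 (CXCL10) and 1.87 (ISG15). Without background correction they were 2.51, 1.67 and 1.73, and all were still called in both settings. SPIB, an Ets transcription factor of B cells, fell by 1.54 ± 0.10 on the log2 scale (SE), from 9.19 ± 0.22 to 7.65 ± 0.11 (SD). Transcripts of MYC and IRF4 fell as well, by 0.49 ± 0.08 and 0.54 ± 0.10 (SE), and MYC was at -0.32 with the fixed offset.

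Of 9041 genes tested, 737 were higher and 603 lower after CC-122, together 14.8% of genes. At a change of at least 1.5-fold the counts were 234 higher and 94 lower, 328 in all. That total was 144 with the fixed offset of 50 in place of 16, and 123 without background correction. The values of the groups did not overlap for 1070 of the called genes, and for 1213 of all genes, where chance alone gives a share of 0.794%. With the bright array, CC-122 replicate 3, left out of the fit but not of the normalization, the counts were 638 higher and 504 lower.

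**Figure D1:**
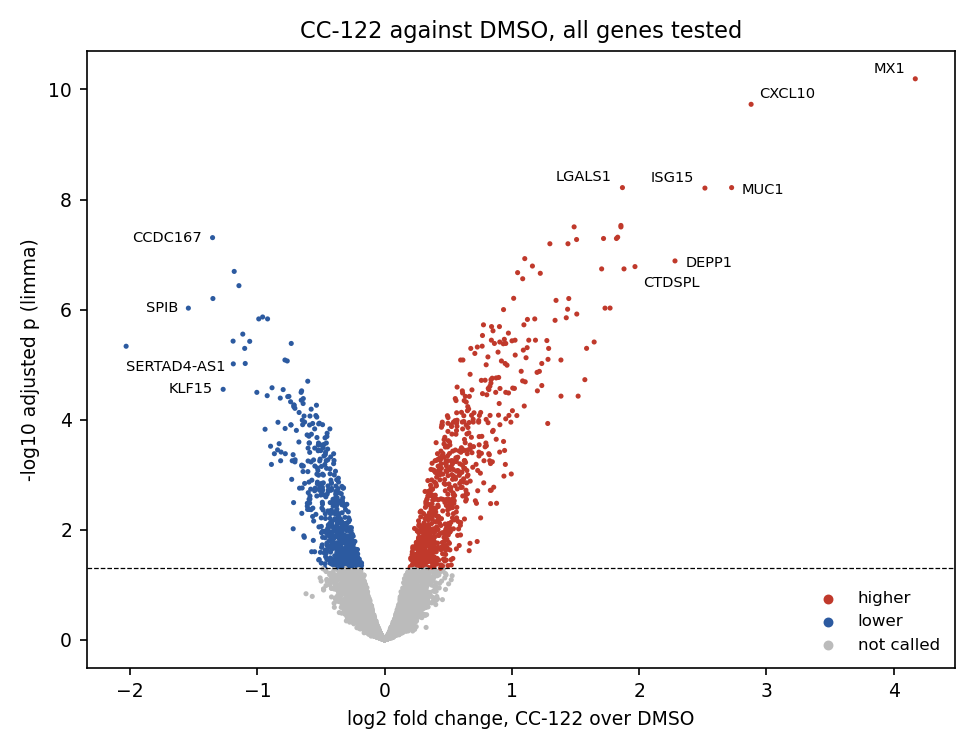
Log2 fold change (horizontal) against minus log10 of the adjusted p from limma (vertical) for the 9041 genes tested, with 1 point per gene. Red points are the 737 genes higher after CC-122, blue points the 603 lower, the dashed line marks an adjusted p of 0.05, and MX1 stands farthest to the right with a fitted log2 fold change of 4.17.

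The 8 largest rises among genes with separate groups were those of MX1, CXCL10, MUC1, ISG15, DEPP1, CTDSPL, IFITM1 and LGALS1. MUC1, a cell surface mucin, rose by 2.73 ± 0.10 on the log2 scale (SE, adjusted p = 6.07e-09) and was detected on 1 of the DMSO arrays. Its other kept probe gave 1.44, and with a fixed background offset MUC1 rose by 1.56. DEPP1, a FOXO target, rose by 2.28 ± 0.12 and was also detected on 1 DMSO array, with 1.25 under the fixed offset. In that setting LGALS1, at 1.70, rose more than MUC1 and DEPP1, so the order of the dim genes is open. CTDSPL, a phosphatase, rose 3.91-fold (a log2 change of 1.26 under the fixed offset), and LGALS1, the lectin galectin-1, rose 3.65-fold by 1.87 ± 0.07 on the log2 scale (SE). IFITM1, which restricts virus entry, rose 3.68-fold. Probes of IFITM1 and its near relatives can share signal.

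The 8 largest falls were those of SERTAD4-AS1, SPIB, CCDC167, CCDC102A, KLF15, NAV2, KREMEN2 and PVRIG. SERTAD4-AS1, an antisense transcript, fell by 2.03 ± 0.17 on the log2 scale (SE) and was detected on 3 of the CC-122 arrays. CCDC167 fell by 1.35 ± 0.06 (adjusted p = 4.92e-08) and PVRIG, an inhibitory immune receptor, fell by 1.18 ± 0.07. KLF15, a Krüppel-like transcription factor, fell by 1.27 ± 0.13 and was detected on 4 of the CC-122 arrays. KREMEN2, a receptor for Dickkopf proteins, fell by 1.19 and NAV2 by 1.19, with their least changed probes at -0.19 and -0.23 and the means of their probes at -0.69 and -0.65. With a fixed background offset the changes were -1.12 (SERTAD4-AS1), -0.72 (CCDC102A) and -0.64 (KLF15), and SPIB at -1.36 and CCDC167 at -1.23 fell more.

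**Figure D2:**
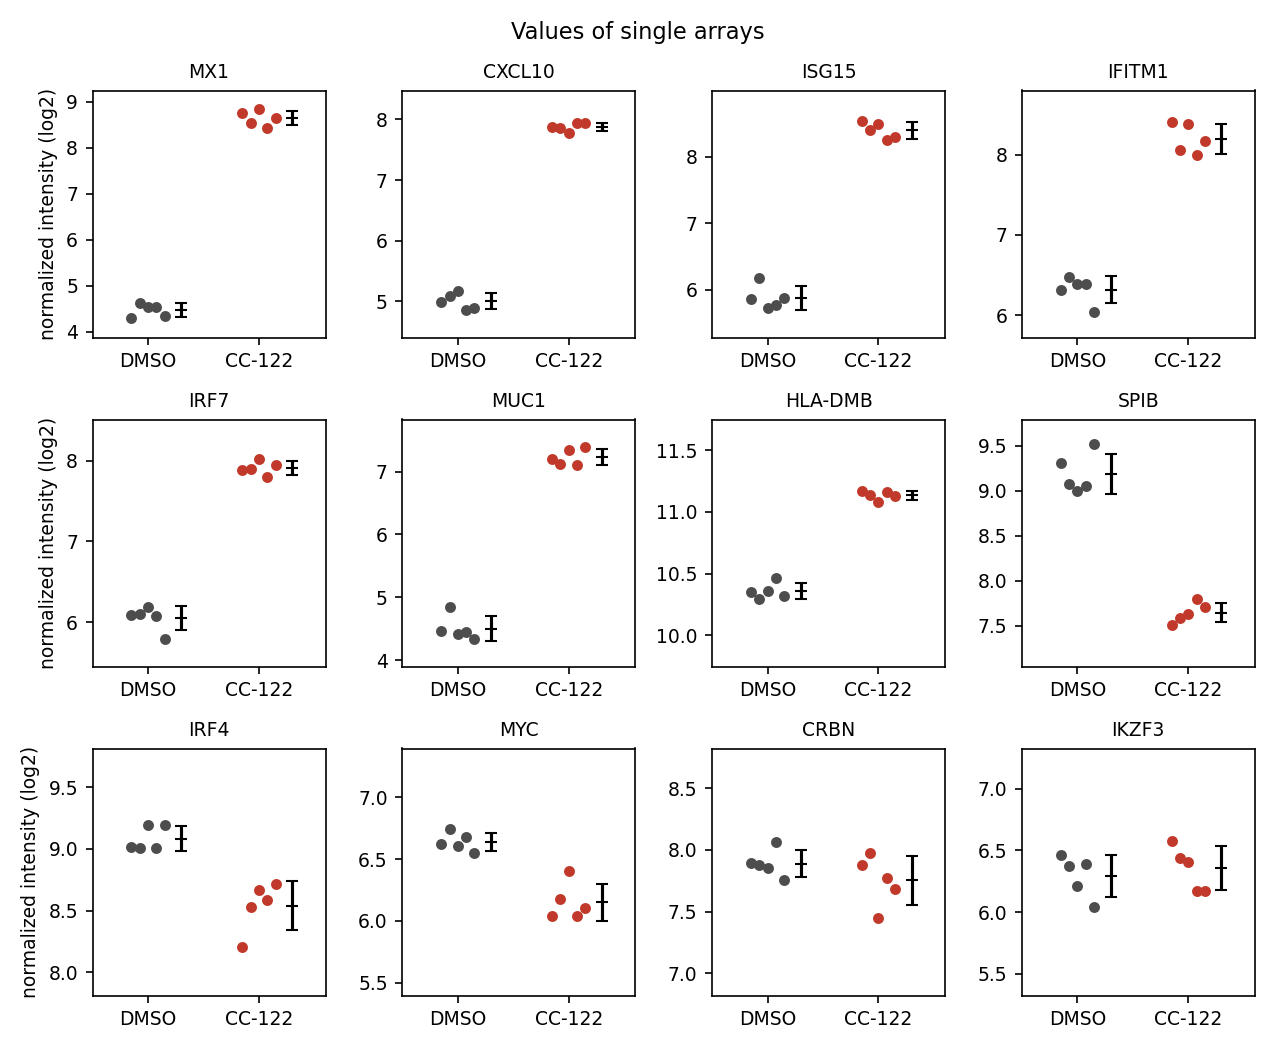
Normalized log2 intensity of 12 genes on each array, DMSO in grey and CC-122 in red, with 1 point per array and the mean with its SD (n = 5) to the right of the points. Vertical axes differ between panels. The groups are apart for MX1, CXCL10, ISG15, IFITM1, IRF7, MUC1, HLA-DMB, SPIB, IRF4 and MYC, and overlap for CRBN and IKZF3.

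Most interferon-stimulated genes rose: 32 of the 41 tested were higher and 9 did not pass the test, with a median log2 fold change of 0.82. Of the 51 members with a named probe 10 were below the filter on dim probes, and without that filter the median was 0.54, as against 0.57 with the filter but no background correction. Adjusted over the list alone, 33 were higher. IRF7, a transcription factor that amplifies the interferon response, rose by 1.86 ± 0.08 on the log2 scale (SE), from 6.05 ± 0.15 to 7.91 ± 0.08 (SD, n = 5). Members beyond the naming rule, picked after their values were seen, were IRF9 at 1.44, BST2 (tetherin) at 1.34 and EIF2AK2, the double-stranded RNA kinase PKR, at 1.12. Another 4 members besides MX1 were undetected on all DMSO arrays: LGALS3BP was at least 2.71-fold higher (adjusted p = 4.83e-08), IFIT2 at least 1.24-fold (adjusted p = 0.0193), CXCL9 at least 1.21-fold (adjusted p = 3.78e-05) and IFI27 at least 1.19-fold (adjusted p = 0.00147). These bounds, like that of MX1, hold only for the background correction used. With the 5 members at their bounds, the median over the tested members was 0.82. Camera placed the list above other genes (adjusted p = 2.43e-34), and the call held with an estimated correlation (adjusted p = 6.69e-05). Without the bright array CC-122 replicate 3, 32 members were higher.

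Genes of the interferon signalling machinery went both ways. Of 16 tested, 3 were higher, 4 lower and 9 not called, with 4 higher and 5 lower when adjusted over the list alone. TLR7, an endosomal sensor of single-stranded RNA, was not detected on DMSO arrays and was at least 1.49-fold higher after CC-122 (adjusted p = 2.27e-04), a bound that holds for the background correction used, as TLR7 differed by 0.41 with a fixed offset. IFNLR1, a chain of the lambda interferon receptor, rose by 0.42 ± 0.07 (SE). JAK1, the receptor-bound kinase, fell by 0.36 ± 0.06, and SOCS1, a feedback inhibitor of JAK kinases, fell by 0.34 ± 0.10 (-0.19 with the fixed offset). The median was -0.002 and the mean 0.03, and camera did not call the list (adjusted p = 0.989). The interferon genes on the list were dim: probes of IFNA1, IFNL1, IFNL2 and IFNL3 were detected on 0 of 10 arrays, that of IFNB1 on 1 and that of IFNG on 3. These counts pool both groups, and interferon genes outside the list were not examined. The fall of SOCS1 lost its call when any of 6 arrays was left out, with adjusted p up to 0.0773. It also lost it without a filter on dim probes (adjusted p = 0.0582) and with the replicate number as a block (adjusted p = 0.0601).

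Cereblon itself and Aiolos did not pass the test as transcripts. CRBN differed by -0.14 (95% interval -0.35 to 0.08, adjusted p = 0.411) and IKZF3 by 0.06 (95% interval -0.16 to 0.28, adjusted p = 0.774). Without DMSO replicate 5, the IKZF3 difference was -0.0055. Among the 16 tested genes of the cereblon pathway and its substrates, 1 was higher, 2 lower and 13 not called, the same counts as when adjusted over the list alone. ZNF692, a zinc finger protein, rose by 0.45 ± 0.12 (SE), while IKZF5 (Pegasus) fell by 0.27 ± 0.08 and MEIS2, a homeobox factor, fell by 0.31 ± 0.09. These 3 calls were weak, since IKZF5 lost its call without any of 7 arrays, MEIS2 without any of 5 and ZNF692 without DMSO replicate 3 or CC-122 replicate 3. IKZF5 also lost it under 6 other settings and MEIS2 without a filter on dim probes. With a fixed background offset ZNF692 was at 0.28 and IKZF5 at -0.15, and the means of probes were -0.14 for IKZF5 and -0.07 for CRBN. The second probe of IKZF5 gave -0.01, and camera did not call the list (adjusted p = 0.915).

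Some antigen presentation genes rose, each by less than 1 log2 unit. Of 17 MHC class I genes tested, 7 were higher and 10 not called, with 9 higher when adjusted over the list alone. HLA-E, HLA-C, HLA-B and HLA-F, heavy chains of class I molecules, rose by 0.62 ± 0.07, 0.60 ± 0.10, 0.56 ± 0.07 and 0.47 ± 0.09 on the log2 scale (SE). HLA-F rose by 0.24 with a fixed background offset, and without background correction HLA-C rose by 0.37 and HLA-DQB1 by 0.29. Of 12 MHC class II genes tested, 6 were higher and 6 not called, with 9 higher and 1 lower when adjusted over the list alone. HLA-DMB and HLA-DMA, the chains of the chaperone that loads peptides on class II molecules, rose by 0.78 ± 0.06 and 0.56 ± 0.07, HLA-DOA by 0.50 ± 0.08 and HLA-DQB1 by 0.47 ± 0.12. Camera called the class I list (adjusted p = 2.42e-05, and adjusted p = 0.0122 with an estimated correlation). It also called the class II list (adjusted p = 4.68e-05), a call lost at adjusted p = 0.0568 with an estimated correlation. HLA genes resemble each other, so their probes can share signal, and without CC-122 replicate 1 a class II member was called lower.

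Of 19 B-cell identity genes tested, 2 rose, 7 fell and 10 did not pass, with 3 higher and 9 lower when adjusted over the list alone. Camera placed the list below other genes (adjusted p = 0.0294), a call lost with an estimated correlation (adjusted p = 0.216). Beside SPIB, CD37, a tetraspanin of mature B cells, fell by 0.65 ± 0.10 (SE), and BCL6, the repressor that runs the germinal centre program, fell by 0.55 ± 0.07. MEF2C, a transcription factor of B-cell activation, rose by 0.50 ± 0.07. The number of members that rose was 1 without DMSO replicate 4. The mean of the list stood apart in DMSO replicate 5, at 8.36 against 8.25 to 8.27 on the other DMSO arrays. With any 1 array left out, 6 to 8 members fell.

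Plasma cell genes changed in both directions. Of 19 tested, 4 were higher, 2 lower and 13 not called, with 8 higher and 2 lower when adjusted over the list alone. The transcription factors IRF4 and PRDM1 (Blimp-1) fell, by 0.54 ± 0.10 and 0.46 ± 0.09 on the log2 scale (SE), with PRDM1 at -0.28 under a fixed background offset. XBP1, which drives the secretory program, rose by 0.40 ± 0.06, and HSP90B1, a chaperone of the endoplasmic reticulum, rose by 0.36 ± 0.06. MZB1 and JCHAIN, picked after their values were seen, were the other members that rose, by 0.31 and 0.29. Camera placed the list above other genes (adjusted p = 0.0322), a call lost with an estimated correlation (adjusted p = 0.232).

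B-cell receptor signalling and NF-kB target genes changed in both directions. Of 24 receptor signalling genes tested, 7 rose, 5 fell and 12 did not pass, with 8 higher and 6 lower when adjusted over the list alone. FCGR2B and PTPN6 (SHP-1), which dampen receptor signals, rose by 0.65 ± 0.08 and 0.47 ± 0.08 on the log2 scale (SE). CD22, an inhibitory coreceptor, fell by 0.78 ± 0.10 and CR2, the complement receptor CD21, fell by 0.50 ± 0.08. With a fixed background offset CD22 was at -0.49, CR2 at -0.24 and PTPN6 at 0.29. Of 23 NF-kB targets tested, 5 rose, 6 fell and 12 did not pass, with 7 higher and 7 lower when adjusted over the list alone. TNF and LTA, cytokines of the same family, rose by 0.90 ± 0.09 and 0.66 ± 0.08, and CD40, a costimulatory receptor, rose by 0.84 ± 0.08. CCL3, a chemokine, fell by 0.64 ± 0.08. Camera called neither list (adjusted p = 0.641 for both), and the NF-kB median of -0.14 and mean of 0.01 differed in sign. The number of receptor signalling genes that fell was 3 without DMSO replicate 1, 2 or 5 or CC-122 replicate 5. It was also 3 without a filter on dim probes and with the replicate number as a block. Probes of FCGR2B and CCL3 can share signal with near-identical genes.

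Some mitotic and DNA replication genes fell, by small amounts, and most did not pass the test. Of 35 G2/M genes tested, 9 fell and 26 did not pass, with a median of -0.20, and 15 were lower when adjusted over the list alone. CENPA, the centromeric histone, fell by 0.40 ± 0.06 on the log2 scale (SE), the kinase TTK by 0.37 ± 0.11, CENPF by 0.36 ± 0.06 and UBE2C, which serves the anaphase-promoting complex, by 0.33 ± 0.06. Of 34 DNA replication genes tested, 7 fell and 27 did not pass, with 8 lower when adjusted over the list alone. ORC6, a subunit of the origin recognition complex, fell by 0.59 ± 0.11, MCM10 by 0.38 ± 0.07, E2F2 by 0.37 ± 0.07 and POLE2 by 0.36 ± 0.08. The other kept probes gave -0.21 for CENPA, -0.55 for UBE2C and -0.26 for MCM10. Camera called the G2/M list (adjusted p = 8.12e-06) and the replication list (adjusted p = 0.0322). Both calls were lost with an estimated correlation, at adjusted p = 0.0521 for G2/M and adjusted p = 0.202 for replication. Without CC-122 replicate 1, and likewise without CC-122 replicate 2, 5 G2/M genes fell, while 16 did so with a fixed background offset and 17 without background correction or with an intensity trend. TTK lost its call when any of 8 arrays was left out, with median scaling and without a filter on dim probes. It also lost it with the replicate number as a block (adjusted p = 0.0904 from limma).

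MYC was the lone call among the 25 tested genes of MYC function and ribosome biogenesis, with 24 not called and the same count when adjusted over the list alone. It fell from 6.64 ± 0.07 to 6.15 ± 0.15 (SD, n = 5, adjusted p = 9.78e-04 from limma). Camera placed the list below other genes (adjusted p = 0.0297, and adjusted p = 0.216 with an estimated correlation). The count that fell was 2 without CC-122 replicate 3 or CC-122 replicate 4, with the mean of a gene's probes or with array weights. It was 3 among probes detected on all 10 arrays, 4 with a fixed background offset or without background correction, and 5, with 1 higher, with an intensity trend.

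Of the apoptosis genes that changed, most rose. Of 26 apoptosis genes tested, 7 rose, 1 fell and 18 did not pass, and the counts were 7 and 1 when adjusted over the list alone. BMF, a BH3-only killer protein, rose by 0.94 ± 0.13 on the log2 scale (SE), and TNFSF10, the death ligand TRAIL, rose by 0.76 ± 0.11 with detection on 1 DMSO array. Genes that block death rose too: BCL2L2 (BCL-W), detected on 1 DMSO array, rose by 0.72 ± 0.11 and BIRC2 (cIAP1) by 0.70 ± 0.10. The sizes for TNFSF10 and BCL2L2 are uncertain, as both were near the background on DMSO arrays: they were 0.33 and 0.34 with a fixed background offset and 0.28 and 0.28 without background correction, all called. BMF rose by 0.61 with that offset. BCL2A1, an inhibitor of apoptosis picked after its value was seen, fell by 0.42. Camera gave an adjusted p of 0.0322, and an adjusted p = 0.193 with an estimated correlation. The number that fell was 2 without background correction, with the mean of probes or with an intensity trend.

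Of 16 p53 targets tested, 2 rose and 14 did not pass, also when adjusted over the list alone. TP53I3 rose by 0.83 ± 0.08 on the log2 scale (SE) and PMAIP1, the BH3-only protein NOXA, by 0.37 ± 0.06. With a fixed background offset TP53I3 rose by 0.41. Of 17 cell cycle inhibitors tested, 3 rose and 14 did not pass, with 8 higher and 1 lower when adjusted over the list alone. GADD45B, a stress-response gene, rose by 0.42 ± 0.09, KLF6 by 0.38 ± 0.07 and FOXO1 by 0.32 ± 0.09 (0.21 without background correction). Camera called neither the p53 list (adjusted p = 0.321) nor the inhibitors (adjusted p = 0.105), while fry called both upward (adjusted p = 0.00149 and 9.54e-04). The probe of CDKN1A (p21) was detected on 1 array and did not pass the filter. With a fixed background offset, without background correction or with an intensity trend, 6 inhibitors were higher, and 1 p53 target was lower in each of these settings and without CC-122 replicate 1. Of the inhibitors, 5 were higher among probes detected on all 10 arrays. Among them 1 was lower with the fixed offset, without background correction or with the replicate number as a block. FOXO1 lost its call without DMSO replicate 2 or DMSO replicate 5.

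Stress genes changed in both directions. Of 20 genes of the unfolded protein and integrated stress response, 6 rose, 3 fell and 11 did not pass, also when adjusted over the list alone. ATF3, a stress-induced transcription factor, rose by 0.45 ± 0.09 on the log2 scale (SE) and DDIT4, an inhibitor of mTORC1, by 0.28 ± 0.06, while CEBPB fell by 0.42 ± 0.08. ATF3 rose by 0.22 with a fixed background offset, and without background correction DDIT4 rose by 0.18 and HSPB1 by 0.64. Of 18 immediate early and heat shock genes, 2 rose, 1 fell and 15 did not pass, with 2 higher and 2 lower when adjusted over the list alone. HSPB1, a small heat shock protein, rose by 1.02 ± 0.08, HSPA1A was undetected on DMSO arrays and at least 1.54-fold higher (adjusted p = 0.00192), and HSPH1 fell by 0.34 ± 0.06. The near-identical gene HSPA1B differed by 0.08 (adjusted p = 0.597), so the HSPA1A value is uncertain, and it was 0.39 with a fixed background offset. Camera called neither list (adjusted p = 0.650 for the unfolded protein list and 0.544 for heat shock). The unfolded protein list had a median of -0.02 and a mean of 0.02, and 3 of its members rose without DMSO replicate 4 or CC-122 replicate 3. Heat shock members called lower numbered 2 without background correction, with median scaling or with an intensity trend, and 1 was higher among probes detected on all 10 arrays.

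Of 16 cholesterol biosynthesis genes tested, 3 fell and 13 did not pass, with 1 higher and 3 lower when adjusted over the list alone. MVD, of the mevalonate pathway, fell by 0.32 ± 0.08 on the log2 scale (SE), INSIG1, which retains the sterol sensor SCAP, by 0.31 ± 0.06 and MSMO1 by 0.23 ± 0.07. Of 21 glycolysis and hypoxia genes, 3 rose and 18 did not pass, also when adjusted over the list alone. SLC2A3, the glucose transporter GLUT3, rose by 0.46 ± 0.11 (0.28 with a fixed background offset), ADM (adrenomedullin) by 0.45 ± 0.06 and DDIT4 as above. Camera called neither (adjusted p = 0.544 and 0.253), while fry called cholesterol genes downward and glycolysis genes upward (adjusted p = 0.00828 and 0.00745). The cholesterol list had a median of 0.01 and a mean of -0.04, with camera pointing down. MSMO1 lost its call without any of 8 arrays, without a filter on dim probes, with the mean of probes and with array weights. It also lost it with the replicate number as a block (adjusted p = 0.0707 from limma). A cholesterol gene was called higher without DMSO replicate 5 and under 5 other settings, and a glycolysis gene lower with an intensity trend.

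Most genes of adhesion, the cytoskeleton and costimulation were not called, and more of the called ones rose than fell. Of 24 tested, 6 rose, 2 fell and 16 did not pass, the same when adjusted over the list alone. ITGB7, an integrin chain that guides lymphocytes to the gut, rose 3.29-fold, from 8.09 ± 0.14 to 9.81 ± 0.10 on the log2 scale (SD, n = 5). CD40 is a member of this list as well. CORO1A, an actin-binding protein, fell by 0.54 ± 0.06 (SE) and RAC2, a GTPase of blood cells, by 0.47 ± 0.06. Camera gave an adjusted p of 0.0208, and an adjusted p = 0.0638 with an estimated correlation.

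Markers of other cell types were mostly undetected, and limma called 0 of the 11 tested. By list, 3 T and NK cell genes, 4 monocyte genes, 2 erythroid or platelet genes and 2 fibroblast or epithelial genes could be tested, with median log2 fold changes of 0.11, 0.27, -0.08 and -0.04. Without the filter on dim probes the medians were -0.03, 0.01, -0.03 and -0.003. Camera gave these lists adjusted p of 0.321, 0.235, 0.692 and 0.880. At an unadjusted p below 0.05 there were 2, the monocyte genes CD68 at 0.37 and AIF1 at 0.50, and these 2 were called when adjusted over the list alone. Monocyte genes called higher numbered 1 with a fixed background offset, 1 without DMSO replicate 2, 1 without DMSO replicate 3 and 2 with an intensity trend. EPCAM was the brightest of the 11, at a mean of 8.89, and differed by -0.13.

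**Figure D3:**
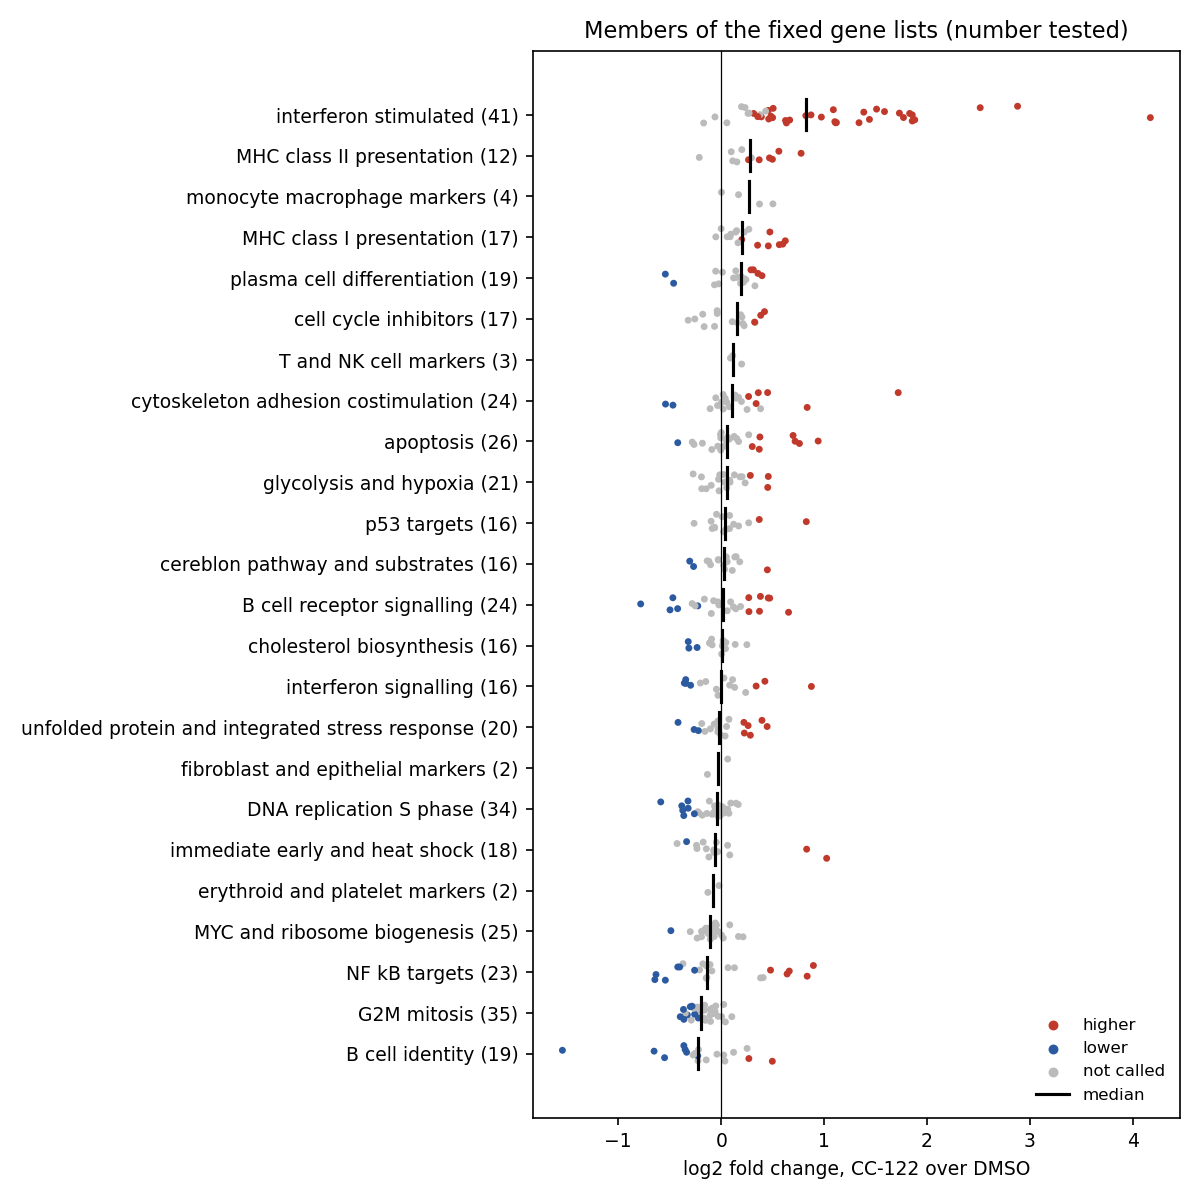
Log2 fold change of CC-122 over DMSO (horizontal) for the tested members of the 24 gene lists (vertical, number tested in brackets), with 1 point per gene. Red points were called higher, blue points lower and grey points not called, and the black bar is the list's median. The interferon-stimulated genes stand highest, with a median of 0.82, and B-cell identity lowest, with a median of -0.23.

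Over the 24 lists, camera called 10 with the preset correlation and 2 with an estimated correlation, the interferon-stimulated genes and MHC class I. Fry, which tests whether a list's genes move one way without comparing them with other genes, called 14. Probes without a gene name here changed too: of 5371 tested, 202 were higher and 141 lower. The largest rise among the called ones was that of ILMN_1674063, by 2.53 on the log2 scale, and the largest fall that of ILMN_1664136, by 1.58.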

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

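The tests for RNA of other cell types and for shared probes among interferon-stimulated genes were chosen only after the result was seen. Values of 1 array standing apart from the other 4 of its group were searched in 216 groups of values, and 13 were found where chance gives about 10.8. The raw median intensity of CC-122 replicate 3 was 108.9 against 74.0 to 81.6 on the other CC-122 arrays, and its raw mean was 410.3 against 201.6 to 254.2. On normalized log2 values, MUC1 stood apart at 4.84 and TLR7 at 4.53 in DMSO replicate 2, both near the background. DEPP1 was at 4.86 in DMSO replicate 4. CCDC167 was at 9.74 and CD22 at 6.89 in DMSO replicate 5, HLA-C was at 6.58 in CC-122 replicate 3, UBE2C was at 10.67 in CC-122 replicate 4 and INSIG1 at 10.10 in CC-122 replicate 2. Of list means, B-cell identity was at 8.36 in DMSO replicate 5, and in CC-122 replicate 1 p53 targets were at 7.46 and cytoskeleton genes at 8.69.

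The brightness of CC-122 replicate 3 may be a gain common to its probes. Among 13419 probes detected on all arrays, its background-subtracted intensity was 2.03 to 2.24 times the mean of the other CC-122 arrays in each of 4 classes of brightness, so the largest ratio was 1.10 times the smallest. After normalization its median absolute distance from the other CC-122 arrays was 0.115 log2 units, within the 0.106 to 0.124 of the others. No biological explanation was tested.

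The rise of interferon-stimulated genes was set against 3 technical explanations. For RNA from other cells, limma called 0 of 73 marker genes higher without a filter on dim probes, with 4 higher at an unadjusted p below 0.05. Most of these markers were too dim to pass the filter, so the test is weak and does not exclude this explanation. With the filter, at most 2 of the 4 tested monocyte genes were called higher under any alternative, with an intensity trend. Of these markers 11 were detected in the cell line, EPCAM at 8.89 and CD247 at 7.27 the brightest. The bright array was argued against, because 32 members were higher in a fit without it, though the normalization still used it. Shared probes were argued against too, because 79.3% of the 29 members outside the near-identical families were higher. An effect of CC-122 is what the comparison of treated and vehicle arrays addresses, and 32 of 41 tested members were higher. The labels do not say that the replicates were separate cultures, and how CC-122 may raise these genes was not tested.

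The fall of mitotic genes was set against a shift shared by genes of like brightness and against the array CC-122 replicate 1. The list's median of -0.20 lay at percentile 0 of 10000 random lists matched on mean expression, the lowest of which was at -0.12. These random lists ignore correlation between genes, estimated at 0.044 for the mitotic list, so their spread may be too narrow. Without CC-122 replicate 1, 5 members were called lower against 9 with it, and without CC-122 replicate 2 the count was also 5. A lower share of dividing cells after CC-122 may account for the fall, a hypothesis that these data do not test, and the estimated correlation leaves the call at adjusted p = 0.0521.

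Other splits of the 10 arrays into groups of 5 were fitted for 100 of the 126 possible, the real one included. In each of 5 results, 1 of the 100 splits, the real one, reached the real value. A share of 1 in 100 is the smallest that this number of splits can give. It argues against a chance division if the arrays are separate samples, and does not exclude one. The other splits all mix treated and vehicle arrays, which puts a treatment effect into their spread, so their counts do not measure how many calls are false. The other splits called at most 0 genes higher, 0 lower, 0 changed at least 1.5-fold and 0 interferon-stimulated genes with limma, against 737, 603, 328 and 32. Their median number of genes at an unadjusted p below 0.05 was 331 and their highest 1337, against 2496. Camera with the preset correlation called up to 8 lists in other splits against 10. It called at least 1 list in 70 of the 99 other splits, with a median of 1.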

How the results depend on the processing

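All alternatives here were planned, and none was chosen only after the result was seen. The counts of higher and lower genes stayed within 1.5 times of 737 and 603 under every alternative run, and the share higher lay between 51.1% and 58.2%. Genes changed at least 1.5-fold numbered 144 with the fixed offset (normexp, offset 50) and 123 without background correction. Both settings by construction shrink the changes of dim genes. Of 81 named genes, the log2 change was over 1.5 times smaller for 26 with that offset, 33 without background correction, 4 with the mean of probes and 1 with array weights, and over 1.5 times larger for 1 with the mean of probes. G2/M genes called lower numbered 16 with that offset, 17 without background correction and 17 with an intensity trend, and the cause was not tested. Leaving out 1 array gave 638 to 701 genes higher, 465 to 564 lower and 315 to 338 changed at least 1.5-fold, with fewer arrays by construction. Members called higher were then 30 to 32 (interferon-stimulated), 5 to 7 (class I) and 5 to 6 (class II, with 0 to 1 lower), and 5 to 9 G2/M genes were lower.

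With an estimated correlation camera called 2 lists, and adjusted p rose to 0.0568 (class II), 0.216 (B-cell identity), 0.232 (plasma cell), 0.0521 (G2/M), 0.202 (replication), 0.193 (apoptosis), 0.216 (MYC) and 0.0638 (cytoskeleton), and the cause was not tested. Fry, which compares no list with other genes, gave 9.54e-04 (cell cycle inhibitors), 0.00149 (p53), 0.00828 (cholesterol) and 0.00745 (glycolysis). IKZF3 was at -0.0055 without DMSO replicate 5, the lowest value with 1 array left out (highest 0.10), and was not called in any setting. Of 801 values of named genes under alternatives 785 kept direction and call and 16 lost the call, and of 810 with 1 array left out 771 kept both and 38 lost the call. All of these losses were among IKZF5, TTK, SOCS1, MEIS2, MSMO1, ZNF692 and FOXO1. Of 960 counts per list 68 moved by over 1.5 times, or from or to 0.

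Arrays share replicate numbers, but only 1 of the 5 same-number pairs had deviations correlated above 0.1 (range -0.01 to 0.14). The main fit was planned without pairing, because the labels do not say that a number marks a shared culture, day or batch. However, 7 of 10 arrays correlated best with their own number, and same-number arrays carry consecutive sample codes in the labels. Pairing therefore stays possible. With the replicate number as a block, 691 genes were higher and 542 lower. In that fit SOCS1 (adjusted p = 0.0601), TTK (0.0904) and MSMO1 (0.0707) were not called, 3 receptor signalling genes and 1 cell cycle inhibitor were lower, and no other named gene changed its call. The slide block was not run. Dim signals limit the rest: the change of a probe near the background depends on its correction.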

Other observations

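The test without HLA-H, HLA-DRB6 and LTB was chosen only after the result was seen. Several genes outside the fixed lists changed strongly, and the ones named here were chosen after their values were seen. ID3, an inhibitor of basic helix-loop-helix transcription factors, rose by 1.51 ± 0.07 on the log2 scale (SE), from 8.29 ± 0.06 to 9.79 ± 0.13 (SD, n = 5). LTB, lymphotoxin beta, rose by 1.49 ± 0.07 and ZFHX3, a homeobox transcription factor, by 1.71 ± 0.10. VCL (vinculin), which links adhesion sites to actin, rose by 1.30 ± 0.06, and the actin regulators RHOC and CORO1B rose by 1.10 ± 0.06 and 1.18 ± 0.08, the latter while its relative CORO1A fell by 0.54. MGLL, monoacylglycerol lipase, rose by 1.43 ± 0.10.

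On the lower side, SULF2, a heparan sulfate sulfatase, fell by 1.10 ± 0.09 on the log2 scale (SE), and OMA1, a mitochondrial protease, by 1.15 ± 0.07. The peroxisome biogenesis genes PEX2 and PEX5 fell by 1.10 ± 0.10 and 0.78 ± 0.07. FBP1, a gluconeogenic enzyme, fell by 0.99 ± 0.07, PTPRCAP, which binds the phosphatase CD45, by 0.96 ± 0.07, and LY86, the partner of the receptor CD180, by 0.92 ± 0.07. CCL3L3, nearly identical to CCL3, fell by 0.74 ± 0.08, and probes of this pair can share signal. No list of these genes was tested for enrichment.

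The HLA genes, TNF and LTA lie near each other on chromosome 6, and a hypothesis is that transcription may have risen across this neighbourhood. Among 62 tested genes between HLA-F and HLA-DPB1 in the GRCh38.p14 annotation that belong to no fixed list, 11 (17.7%) were higher against 7.43% of 8544 genes elsewhere, 2.39 times the share (two-sided Fisher exact p = 0.00586). Genes are not independent replicates. Without HLA-H and HLA-DRB6, which resemble other HLA genes, and without LTB, 8 of 59 (13.6%) were higher (two-sided Fisher exact p = 0.0808), a test that leaves out genes picked because they rose and so raises p by construction. Whether the excess rests on these 3 genes stays open.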
